A study of Gallus gallus with 8 samples.

How the data were processed

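RNA was measured in green fluorescent (GFP+) cells sorted from chicken (Gallus gallus) trunk neural crest, the migratory embryonic population that gives rise to peripheral neurons, glia and pigment cells. Cells had received Cas9 with a scrambled guide RNA or with a guide against DLC1, PHF5A or SF3B1, per the labels. SF3B1 and PHF5A encode subunits of SF3b, the part of the U2 small nuclear ribonucleoprotein that recognises the branch point of introns. Each of the 4 groups held 2 libraries. The 2 libraries of a knockout carried 2 different guides, so their spread held guide and library differences together. The labels number the control libraries as replicates and say nothing of separate cultures or embryo pools, so p-values measure only the spread between these libraries.

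Per the labels' protocols, about 50000 GFP+ cells were collected per treatment, RNA was treated with DNase, samples of high RNA integrity were selected, and libraries were made with the Illumina Stranded mRNA Prep kit, which selects polyadenylated RNA. Per the submitters' processing notes, the tools used were FastQC 0.12.1, Trimmomatic 0.39, STAR 2.7.11b and featureCounts 1.5.3 of the Subread package, with genome build GRCg6a. The strand setting and the annotation release are not given in the sources used here. The authors deposited raw counts per Ensembl gene ID for 30862 features, with chromosome, start, end, strand and length. The length equalled the distance from start to end in 100% of rows, so each gene's length was its whole genomic span. Counts over a whole span can take in reads from introns and from genes nested in them, which was not checked, and the counts of features that overlap on either strand could not be told apart with certainty. All 8 columns of counts matched a labelled sample.

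The deposited IDs were not paired with gene names. A table of 25635 RefSeq genes of assembly GRCg7b was at hand, in which 0 genes carried an Ensembl ID, so 0 IDs were matched. Gene names, the level of each targeted gene in its own knockout, and 36 lists of named genes chosen before the data were examined (spliceosome, neural crest, lineage, stress and cell cycle genes among them) were therefore not analysed here. The comparisons used instead the properties that the deposited table holds for every feature, which are its chromosome and its span. These groups were chosen after the table was seen to hold no names. Coordinates are on GRCg6a, as deposited.

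Total counts ran from 18226753 to 34698250 per library. The floor of 3 counts corresponded to 0.165 CPM (counts scaled to a common library total) in the shallowest library and to 0.0865 CPM in the deepest. Wilson 95% intervals of the shares of counts given per library were at most 0.02 percentage points to either side for mitochondrial counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

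All 8 libraries entered one fit with edgeR 4.0.16 (R 4.3.3): genes were kept by filterByExpr (15619 of 30862), scaled by trimmed mean of M-values (TMM), and tested by the quasi-likelihood F-test with robust dispersion. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were obtained from the fold change and the F statistic. The comparisons, fixed before the data were examined, were each knockout against control, each pair of knockouts, the mean of the 3 knockouts against control, and the genes called in the same direction in all 3. CPM values given as mean ± SD used TMM-scaled library sizes. Log2 CPM for correlations, principal components and medians per library used a prior count of 2. The rule for named genes asked for a symbol, so it was applied without that clause and cut to the 2 rising and 2 falling IDs of each knockout with the largest absolute log2 fold change among called genes that had both guide libraries on one side of both controls and a mean of at least 5 CPM in either group.

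Groups of genes by chromosome (at least 20 tested genes, the mitochondrial chromosome included) and by span, 43 in all, were compared with the other tested genes by camera in limma 3.58.1 with a preset correlation of 0.01, then with an estimated correlation, and tested by fry. P-values were adjusted over the 258 tests of the 6 comparisons. The span groups leave out mitochondrial features. The span difference of a comparison is the median log2 fold change of nuclear genes of 30 to 100 kb minus that of nuclear genes of up to 3 kb. The neighbour test counted pairs of adjacent tested genes called in the same direction and compared it with 1000 permutations of the calls along the genome. Correlations between knockouts were set beside 20 simulated data sets in which no group differed from control, since all 3 comparisons share the same control libraries.

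The test was run on simulated counts with the real means and library sizes, for DLC1 knockout against control over 15619 genes. It recovered 1 of 50 genes changed 1.5-fold, 13 of 50 changed 2-fold, 33 of 50 changed 3-fold and 46 of 50 changed 5-fold, none with the wrong sign, with 7 false calls among 100. Camera recovered 5 of 5 simulated groups shifted by 0.5 on the log2 scale and called 0 of 100 unshifted ones. The simulated counts matched real means and library sizes, not the correlation between genes. In DLC1 knockout against control the estimated correlation was 0.743 for mitochondrial, 0.654 for W and 0.251 for Z features. It was 0.134 for spans of 1 to 3 kb and 0.0888 over 300 kb. These exceed the preset, while spans of 10 to 30 kb (0.00714) lay below it. False calls of camera with the preset at such correlations were therefore not tested.

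The alternatives fixed before the data were examined were median-ratio size factors, library size alone, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, dispersion without the robust option, the replicate number as a block, only the groups compared in the fit, and each library left out in turn. Thinning all libraries to the smallest total, leaving out mitochondrial features, leaving out Z and W features, and the W chromosome share as a covariate were added after the data were seen. The closing section gives their effect.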

Results

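The series compared sorted trunk neural crest cells after Cas9 knockout of DLC1, PHF5A or SF3B1 with cells given a scrambled guide, and asked how each knockout altered the transcriptome. Each group held 2 libraries. The controls held 19163114 and 18226753 counts and the SF3B1 knockouts 19565587 and 18545207. The DLC1 knockouts held 34460321 and 34698250 counts and the PHF5A knockouts 34371525 and 33864758, so depth followed the groups. Reads were counted in 18275 and 18471 features of the controls and in 19124 to 20415 features of the knockout libraries.

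The 2 libraries of each group differed by far more than sampling noise, with a chi-square per degree of freedom between 40.6 in the controls and 191 in the PHF5A knockouts, so the counts gave no sign of a duplicated library. The first principal component of log2 CPM took 44.7% of the variance and placed both controls (-65.8 and -72.0) apart from all 6 knockout libraries. The second took 24.0% and placed the SF3B1 libraries lowest (-35.8 and -44.1) and those of DLC1 highest (25.8 and 52.6). The PHF5A guides (19.3 and -11.4) and the controls (9.35 and -15.7) lay between. Pearson's r of log2 CPM across genes was 0.979 between the controls and 0.984 to 0.988 between the 2 guides of a knockout. Between libraries of different knockouts it ran from 0.961 to 0.987. The highest of these, between the guide 1 libraries of DLC1 and PHF5A, exceeded the 0.984 between the 2 PHF5A guides.

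Mitochondrial transcripts made up less of the counts in every knockout. They took 23.7% ± 3.16 of the counts in controls (SD, n = 2), 12.7% ± 4.28 in DLC1 knockout, 13.8% ± 8.17 in PHF5A knockout and 13.7% ± 6.03 in SF3B1 knockout (SD, n = 2 each). All 6 knockout libraries lay below both controls (two-sided exact permutation test over 28 splits of the libraries, p = 0.0357, which is the smallest the design allows; 0.0714 after Benjamini-Hochberg adjustment over 4 measures). Within each knockout the guide 1 library held the lower share, 9.65% against 15.7% for DLC1, 8.01% against 19.6% for PHF5A and 9.44% against 18.0% for SF3B1. The share of nuclear counts on the female-specific W chromosome was 0.198% and 0.00279% in the 2 controls. The second of these rested on 399 reads, with a Wilson 95% interval of 0.00253% to 0.00307%. It ran from 0.0402% to 0.259% in the knockouts.

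**Figure D1:**
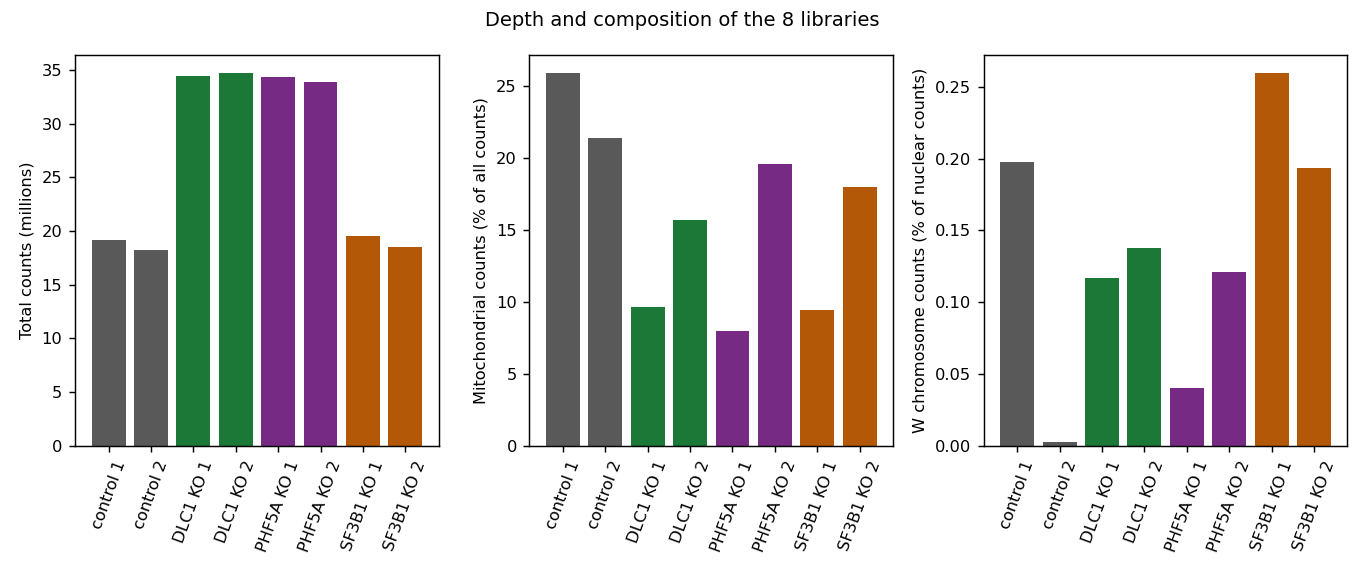
Bars give, for each of the 8 libraries, total counts (left), mitochondrial counts as a percent of all counts (middle) and W chromosome counts as a percent of nuclear counts (right); colours mark the 4 groups. Mitochondrial shares were 25.9% and 21.4% in the controls and 8.01% to 19.6% in the knockouts, and the W share of control 2 was 0.00279%.

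Knockout of DLC1 was compared with control over 15619 genes. Among the genes called, those with long genomic spans mostly rose and those with short spans mostly fell. Of 236 genes spanning over 300 kb, 70 rose and 2 fell, with a median log2 fold change of 0.68. Of 3528 genes of 30 to 100 kb, 601 rose and 86 fell, with a median of 0.34. Of 4298 genes of 3 to 10 kb, 211 rose and 578 fell, with a median of -0.18, and of 1379 genes of 1 to 3 kb, 73 rose and 214 fell, with a median of -0.29. Camera with a preset correlation called each of these groups (adjusted p = 2.06e-10 for spans over 300 kb, 2.4e-06 for 30 to 100 kb, 7.04e-07 for 3 to 10 kb and 6.69e-05 for 1 to 3 kb), and none was called with an estimated correlation (adjusted p = 0.962 for each). Fry called 0 of the 43 groups of genes in this and in each other comparison. With library size as the only scaling, the median was 0.20 for 3 to 10 kb and 0.06 for up to 3 kb, both below the median of all genes, which was then 0.48.

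The 37 mitochondrial features had a median log2 fold change of -1.24 in DLC1 knockout, with 8 that fell and 0 that rose (camera adjusted p = 1.14e-05; 0.962 with an estimated correlation). Against the mean of the controls their median log2 ratio was -1.56 and -0.746 in the guide 1 and guide 2 libraries. Genes on chromosome 25 had a median of -0.27 (12 rose and 37 fell of 192) and those on chromosome 27 a median of -0.13 (14 rose and 44 fell of 265), with camera adjusted p of 0.000359 and 0.00648, both 0.962 with an estimated correlation. The median span of tested genes was 20.6 kb on the large chromosomes (1 to 10) and 9.81 kb on the small ones (11 to 33). Among genes of 1 to 3 kb the median log2 fold change was -0.129 on the large and -0.425 on the small chromosomes. It was -0.142 and -0.22 at 3 to 10 kb, 0.103 and 0.099 at 10 to 30 kb, and 0.327 and 0.363 at 30 to 100 kb. Within the groups of short span, genes on the small chromosomes thus had the lower median. Span inside each group and expression were not matched, and the contrast was not tested, so whether span accounts for it stays open. With library size as the only scaling, the medians of chromosomes 25 and 27 were 0.10 and 0.24, against a median of all genes of 0.48.

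In all, edgeR's quasi-likelihood test called 2847 genes in DLC1 knockout, of which 1616 rose and 1231 fell, 984 and 625 of them by at least 2-fold. The calls numbered 1458 without control 1, 347 without control 2, 302 without the guide 1 library and 938 without the guide 2 library, and 1839 with the W share as a covariate. The share that rose was 56.8%, against 47.4% with median-ratio size factors, 46.5% with DESeq2 and 89.4% with library size as the only scaling, which moved the median of all genes from 0.10 to 0.48.

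ENSGALG00000030129, on the unplaced scaffold KZ626834.1 (244710 to 298175, minus strand), held 0 reads in both controls and 309 and 97 in the DLC1 knockouts. Its level there was 5.41 ± 3.56 CPM (SD, n = 2). Its reads pooled over both knockout libraries lay 56.2-fold above the floor of 3 counts over both controls (edgeR adjusted p = 0.00477). ENSGALG00000048209, on chromosome 19 (195297 to 199262, minus strand), rose from 0.267 ± 0.102 to 24.8 ± 4.51 CPM (SD, n = 2; log2 fold change 6.52, SE 0.353, edgeR adjusted p = 4.62e-05). ENSGALG00000030994, on chromosome 25 (2622590 to 2624230, plus strand), fell from 14.7 ± 0.778 to 0.791 ± 0.102 CPM (n = 2; log2 fold change -4.21, SE 0.339, edgeR adjusted p = 0.000591). ENSGALG00000056015, on chromosome 16 (2781457 to 2794978, minus strand), fell from 27 ± 0.912 to 2.76 ± 0.427 CPM (n = 2; log2 fold change -3.29, SE 0.259, edgeR adjusted p = 0.000591). Both of these features were lower in PHF5A knockout as well, with log2 fold changes of -4.21 and -3.92 (edgeR adjusted p = 0.000473 and 0.000238).

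Knockout of PHF5A, an SF3b subunit, gave the same order by span. Of 3528 genes of 30 to 100 kb, 1103 rose and 156 fell, with a median log2 fold change of 0.43, and of 236 genes over 300 kb, 62 rose and 5 fell, with a median of 0.51. Of 4298 genes of 3 to 10 kb, 333 rose and 964 fell (median -0.22), and of 1379 genes of 1 to 3 kb, 115 rose and 352 fell (median -0.40). Camera adjusted p was 1.69e-07, 0.000195, 1.69e-07 and 2.06e-05 for these 4 groups, and 0.962 for each with an estimated correlation. With library size as the only scaling the median was 0.20 for 3 to 10 kb and 0.02 for up to 3 kb, against 0.53 for all genes. The mitochondrial features had a median of -0.89, with 4 of 37 called, all falling (camera adjusted p = 0.000761; 0.962 with an estimated correlation), and the guide 1 and guide 2 libraries stood at -1.87 and -0.337. Chromosome 25 had a median of -0.35, with 17 genes that rose and 55 that fell of 192 (camera adjusted p = 0.000113; 0.962 with an estimated correlation), and the libraries stood at -0.539 and -0.167. The median of chromosome 25 was 0.07 with library size as the only scaling.

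In PHF5A knockout 4890 genes were called (edgeR): 2792 rose and 2098 fell, 1806 and 966 of them by at least 2-fold. Without control 1 the number was 2823, without control 2 it was 2268, and without the guide 1 library it was 3101. The share that rose was 57.1%, against 49.6% with median-ratio size factors, 48.7% with DESeq2 and 87.7% with library size as the only scaling, which moved the median of all genes from 0.10 to 0.53.

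The 2 rising features named for DLC1 also led here. ENSGALG00000030129 reached 11.7 ± 5.40 CPM (SD, n = 2), 114-fold above the control floor in pooled reads (edgeR adjusted p = 0.0014), and ENSGALG00000048209 reached 21.1 ± 3.57 CPM (n = 2; log2 fold change 6.29, SE 0.354, edgeR adjusted p = 6.72e-05). ENSGALG00000000302, on chromosome 26 (805741 to 818458, plus strand), fell from 59.1 ± 43.2 to 0.376 ± 0.0346 CPM (n = 2; log2 fold change -7.27, SE 0.950, edgeR adjusted p = 0.00219). The call was lost when either PHF5A library was left out (adjusted p = 0.0681 without guide 1 and 0.0555 without guide 2). ENSGALG00000009844, on chromosome 5 (32480274 to 32485870, plus strand), fell from 27.4 ± 20.5 to 0.791 ± 0.126 CPM (n = 2; log2 fold change -5.11, SE 1.41, edgeR adjusted p = 0.0421), and lost its call without either PHF5A library (0.252 and 0.218), with library size as the only scaling (0.0533) and with the replicate number as a block (0.0879).

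Knockout of SF3B1, the largest SF3b subunit, shared the shift at intermediate spans and departed from it at the longest ones. Of 3528 genes of 30 to 100 kb, 647 rose and 90 fell (median log2 fold change 0.24), and of 1379 genes of 1 to 3 kb, 58 rose and 115 fell (median -0.27), with camera adjusted p of 0.000592 for both (0.962 with an estimated correlation). Genes of up to 3 kb had a median of -0.26, which was 0.17 with library size as the only scaling. Genes over 300 kb had a median of -0.07, with 17 that rose and 7 that fell of 236 (camera adjusted p = 0.551). That median was 0.38 with library size as the only scaling, below the median of all genes, which was then 0.49.

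The mitochondrial features had a median of -1.32 in SF3B1 knockout, with 13 of 37 called, all falling (camera adjusted p = 1.58e-11; 0.962 with an estimated correlation), and the guide 1 and guide 2 libraries stood at -1.97 and -0.872. Genes on the Z chromosome had a median of -0.23, with 36 that rose and 71 that fell of 752 (camera adjusted p = 0.00282), and those on W a median of 1.24, with 5 that rose and 0 that fell of 38 (1.25e-07). Both had an adjusted p of 0.962 with an estimated correlation. With library size as the only scaling the Z median was 0.21, again below that of all genes. The 2 controls differed on these chromosomes by more than the 2 SF3B1 libraries did, at -0.23 and 0.23 on Z around their own mean and 1.98 and -1.98 on W.

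In SF3B1 knockout 2507 genes were called (edgeR), of which 1721 rose and 786 fell, 1212 and 277 of them by at least 2-fold. Without control 1 the number was 891, without control 2 it was 587, without the guide 1 library 149 and without the guide 2 library 1575. With no filter on low counts it was 4056. The share that rose was 68.6%, against 56.9% with median-ratio size factors, 50.7% with DESeq2 and 97.4% with library size as the only scaling (3951 calls, median of all genes 0.49 in place of 0.04). With the W share as a covariate 2 genes were called. The 1721 rising genes then had a median log2 fold change of 1.30 in place of 1.31, while their median SE went from 0.279 to 0.387 and the residual degrees of freedom from 4 to 3.

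ENSGALG00000030129 reached 13.7 ± 3.55 CPM in SF3B1 knockout (SD, n = 2), 134-fold above the control floor in pooled reads (edgeR adjusted p = 0.00403), and ENSGALG00000048209 reached 19.1 ± 0.0325 CPM (n = 2; log2 fold change 6.15, SE 0.355, edgeR adjusted p = 8.83e-05). With the W share as a covariate the first had an adjusted p of 0.0872. ENSGALG00000029657, on chromosome 25 (2088584 to 2094743, plus strand), fell from 16.7 ± 0.242 to 0.639 ± 0.236 CPM (n = 2; log2 fold change -4.72, SE 0.427, edgeR adjusted p = 0.0031). ENSGALG00000040296, a feature of 74 bp on the mitochondrial chromosome (3967 to 4040, plus strand), fell from 6.86 ± 7.20 to 0.515 ± 0.183 CPM (n = 2; log2 fold change -3.75, SE 0.879, edgeR adjusted p = 0.0226). Its adjusted p was 0.151 without control 1, which held 184 of the 210 control reads, 0.188 and 0.0674 without the guide 1 and guide 2 libraries, 0.0686 with limma-voom, 0.0511 with the replicate number as a block and 0.0607 with the W share as a covariate.

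**Figure D2:**
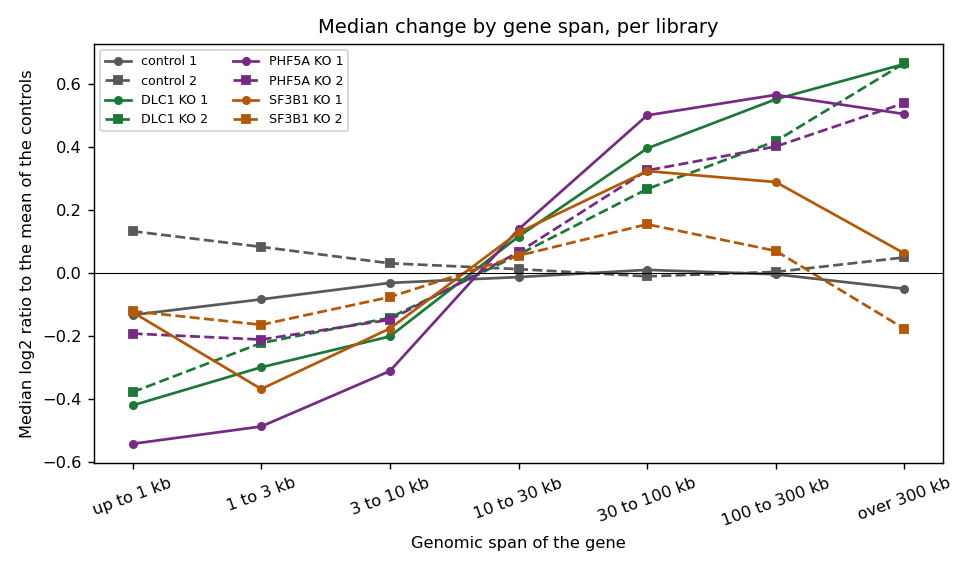
Points give the median log2 ratio to the mean of the 2 controls of nuclear genes in 7 groups of genomic span, one line per library (solid, library or guide 1; dashed, library or guide 2). At 30 to 100 kb the 6 knockout libraries lie between 0.155 and 0.501, above both controls, and at over 300 kb the SF3B1 libraries lie at 0.06 and -0.18 while those of DLC1 and PHF5A lie between 0.505 and 0.667.

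The span difference, nuclear genes of 30 to 100 kb minus those of up to 3 kb, was 0.65 in DLC1, 0.82 in PHF5A and 0.50 in SF3B1 knockout on the log2 scale. With no filter on low counts it was 0.314, 0.394 and 0.159, and without the guide 1 library of SF3B1 it was 0.309 in that knockout. Per library it was 0.704 and 0.5 for the DLC1 guides, 0.995 and 0.535 for the PHF5A guides and 0.658 and 0.318 for the SF3B1 guides, against 0.0964 and -0.0964 for the controls around their own mean. Among the genes of highest mean expression it was 0.904, 1.07 and 0.676 for DLC1, PHF5A and SF3B1, and among those of lowest expression 0.485, 0.540 and 0.338. Among the highest, long genes in SF3B1 knockout had a median of 0.037 and short ones -0.639. Among the lowest, the short genes stood at -0.0413, 0.042 and 0.116 and the long ones at 0.444, 0.582 and 0.454. A rise of long genes and a fall of short ones were thus not both seen at each level.

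Whether the knockouts changed the same genes was asked next. Of 15619 genes, 1118 were called in the same direction in all 3, of which 743 rose and 375 fell. Independent lists of the same sizes would share 31.8 rising and 8.32 falling genes. DLC1 and PHF5A shared 1362 rising and 1075 falling calls, with 3 called in opposite directions. SF3B1 shared 765 and 389 with DLC1, with 5 in opposite directions, and 1386 and 574 with PHF5A, with 1 in opposite directions. The number called in all 3 was 481 without control 1, 110 without control 2, 152 and 596 without the guide 1 and guide 2 libraries of DLC1 and 112 without the guide 1 library of SF3B1. It was 2002 with library size as the only scaling (1960 of them rising), 1933 with no filter and 2 with the W share as a covariate. With the replicate number as a block it was higher still, as given in the closing section.

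Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.828 between DLC1 and PHF5A, 0.645 between DLC1 and SF3B1 and 0.808 between PHF5A and SF3B1. Simulated unchanged groups gave 0.569, 0.554 and 0.551. The covariances were 0.649, 0.452 and 0.661, each set against about 0.081 in the simulations, an excess of 0.568, 0.371 and 0.580. With each knockout set against a different control library, r was 0.651 and 0.538 for DLC1 and PHF5A, 0.463 and 0.339 for DLC1 and SF3B1, and 0.594 and 0.573 for PHF5A and SF3B1. Against the mean of the controls, the mean of the 3 knockouts differed in 4805 genes (edgeR), of which 2620 rose and 2185 fell. The number was 2318 without control 1 and 1430 without control 2, and the share that rose was 54.5%, against 46% with median-ratio size factors, 47.2% with DESeq2 and 90.0% with library size as the only scaling.

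**Figure D3:**
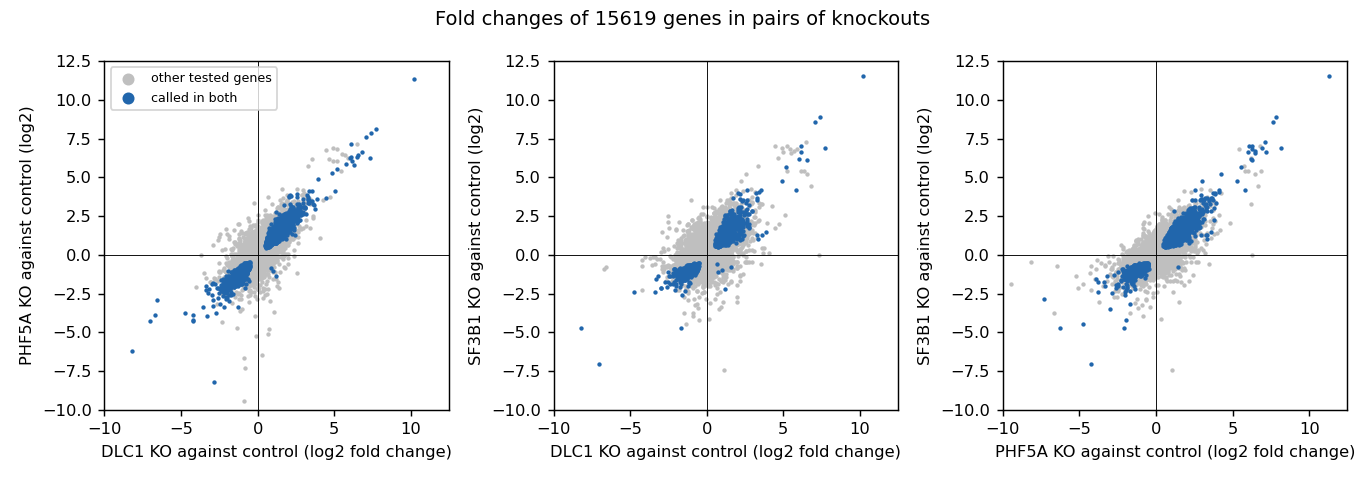
Each point is 1 of 15619 tested genes, with its log2 fold change against control in 2 knockouts on the axes; blue points were called in both comparisons and grey points are the other tested genes. Genes called in both lie mostly in the lower left and upper right quadrants, with 3, 5 and 1 genes called in opposite directions in the 3 panels.

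The 2 guides of a knockout were compared by their log2 ratios, each to the control of the same number. Across genes, Pearson's r was 0.5 for DLC1, 0.717 for PHF5A and 0.623 for SF3B1, and Spearman's rho was 0.535, 0.765 and 0.681. With the controls exchanged, r was 0.649, 0.584 and 0.584. Different knockouts, each the mean of its 2 libraries, were also set against different controls. That gave r of 0.651 and 0.538 for DLC1 and PHF5A, 0.463 and 0.339 for DLC1 and SF3B1, and 0.594 and 0.573 for PHF5A and SF3B1. The guides of DLC1 and of SF3B1 agreed more closely than these 2 knockouts did with each other. The values of all guides overlapped those of the other pairs of knockouts. A mean of 2 libraries carries less noise than a single library, so the values within and between knockouts are not like measures. How far guide agreement separates an effect of the target from changes common to the knockouts was therefore not settled.

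The knockouts were then compared with each other, which leaves the control out of the difference. Between PHF5A and DLC1 knockout, edgeR called 1 gene, which was lower in PHF5A, with 1906 genes at an unadjusted p under 0.05. DESeq2 called 280 genes, limma-voom 2, edgeR with no filter 722, and edgeR on these 4 libraries alone 73. Leaving out the guide 1 library of PHF5A gave 69. Genes over 300 kb had a median difference of -0.19 with no gene called (camera adjusted p = 0.00212; 0.962 with an estimated correlation), and ENSGALG00000000302 differed by -6.47 (SE 0.931, edgeR adjusted p = 0.0871).

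Between SF3B1 and DLC1 knockout the longest genes were lower in SF3B1. The DLC1 libraries held more counts, so a separate sequencing run cannot be told apart from a difference between the targets. After thinning to the smallest total 751 genes differed (edgeR), while genes over 300 kb were not examined after thinning. Of 236 genes over 300 kb, 52 were lower and 0 higher in SF3B1 knockout, with a median difference of -0.64 (camera adjusted p = 5.2e-17; 0.962 with an estimated correlation, 0.0241 before adjustment). Of 1219 genes of 100 to 300 kb, 74 were lower and 6 higher, with a median of -0.24 (camera adjusted p = 9.69e-06, and 0.962 with an estimated correlation). Z genes had a median difference of -0.25, with 33 lower and 4 higher of 752 (camera adjusted p = 5.69e-05). The medians were 0.70 for W genes and -0.30 for mitochondrial features (camera adjusted p = 0.00212 and 0.0125). Each of these groups had an adjusted p of 0.962 with an estimated correlation. ENSGALG00000030994, a falling feature named for DLC1 knockout, was 3.50 higher in SF3B1 than in DLC1 knockout on the log2 scale (SE 0.334, edgeR adjusted p = 0.00317), at 9.01 ± 2.74 against 0.791 ± 0.102 CPM (SD, n = 2). In all, 778 genes differed (edgeR), 394 higher and 384 lower in SF3B1 knockout. The number fell to 1 without the guide 2 library of DLC1, to 33 and 25 without the guide 1 and guide 2 libraries of SF3B1 and to 16 with the W share as a covariate. It rose to 1636 and 1580 without the guide 1 and guide 2 libraries of PHF5A, to 2578 with no filter, to 1866 with DESeq2 and to 1949 with these 4 libraries alone. It was 474 at a mean of at least 5 CPM and 329 with library size as the only scaling.

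Between SF3B1 and PHF5A knockout, genes over 300 kb had a median difference of -0.49, with 10 lower and 0 higher of 236 in SF3B1 knockout (camera adjusted p = 8.86e-15; 0.962 with an estimated correlation). Genes on the Z chromosome had a median difference of -0.42, with 17 of 752 lower and 0 higher, and 18.4% of them above 0 (camera adjusted p = 9.22e-15; 0.962 with an estimated correlation). With the W share as a covariate that median was -0.0892. ENSGALG00000029657 was lower in SF3B1 knockout by -2.67 on the log2 scale (SE 0.423, edgeR adjusted p = 0.0267). The PHF5A libraries also held more counts than those of SF3B1, so a separate sequencing run stays open here as well. After thinning to the smallest total 167 genes differed (edgeR). In all, 174 genes differed without thinning (edgeR), 57 higher and 117 lower in SF3B1 knockout. The number was 108 and 110 without control 1 and control 2, 28 and 25 without the guide 1 and guide 2 libraries of DLC1, and 31 and 3 without those of SF3B1. With these 4 libraries alone it was 0 (2344 genes at an unadjusted p under 0.05), with the W share as a covariate 0 (1398 genes), with library size as the only scaling 52, with DESeq2 664 and with no filter 1134.

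**Figure D4:**
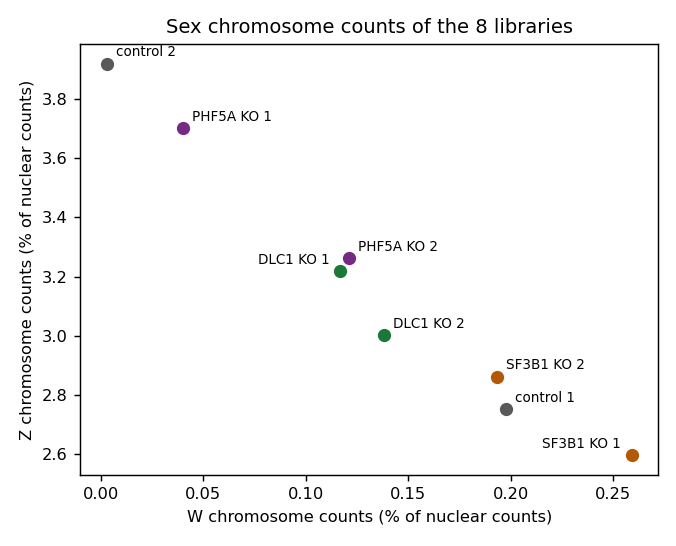
Each point is 1 of 8 libraries, with W chromosome counts on the horizontal axis and Z chromosome counts on the vertical axis, both as a percent of nuclear counts; colours mark the 4 groups. The libraries run from control 2 (0.00279% W, 3.92% Z) to the guide 1 library of SF3B1 (0.259% W, 2.60% Z).

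Called genes lay next to each other along the chromosomes more often than permuted calls did. Calls also followed span, and whether neighbours of like span account for this excess was not tested. Of 13619 pairs of adjacent tested genes, 291 were called in the same direction in DLC1 knockout (mean of 1000 permutations 238.6, highest 296, permutation p = 0.002). The number was 804 in PHF5A knockout (698.7, highest 777) and 272 in SF3B1 knockout (211.3, highest 259), with a permutation p of 0.001 in both, the smallest that 1000 permutations give. On chromosome 6, 5 adjacent genes rose in DLC1 knockout (36216495 to 36262558, median log2 fold change 1.61) and 6 rose in SF3B1 knockout from the same start (to 36277895, median 2.23). On chromosome 33, 7 adjacent genes rose in PHF5A knockout (7601086 to 7638408, median 1.76) and 6 fell in DLC1 knockout (5216342 to 5426967, median -1.27). These runs were picked among the longest. A run of 7 also rose on chromosome 27 in PHF5A knockout, and runs of 6 on chromosomes 13 and 23 in SF3B1 knockout. The permutations scored pairs of neighbours only, so the length of a run was not tested.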

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

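The tests of depth for gene span, of the mitochondrial share, of the shared controls and of separate handling were chosen after the results were seen, as were the correlations between libraries.

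For a closer look, 5 differences between knockouts were taken from a larger number. Camera with a preset correlation called 4 groups of genes between PHF5A and DLC1, 7 between SF3B1 and DLC1 and 14 between SF3B1 and PHF5A knockout. The median log2 fold change of Z chromosome genes differed between SF3B1 and PHF5A knockout by -0.42, and that of W genes by 1.42 in the opposite direction. Genes over 300 kb differed by -0.64 between SF3B1 and DLC1 knockout. Mitochondrial features differed by -0.40 between SF3B1 and PHF5A knockout, less than the 2 libraries of either group differed from each other (-1.97 and -0.872 in SF3B1, -1.87 and -0.337 in PHF5A, each against the controls). Each of these 4 passed camera with a preset correlation and did not with an estimated one (adjusted p = 0.962). All 5 genes called in opposite directions in DLC1 and SF3B1 knockout were also called in the test of the difference, which their choice made all but certain.

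In the sex chromosome pattern, Z and W moved in opposite directions. Over the 8 libraries the Z share fell as the W share rose (Pearson r = -0.986, exact permutation p = 4.96e-05, 9.92e-05 after adjustment over 2 relations; Spearman rho = -0.976, exact p = 0.000397), and r was -0.982 without the 2 libraries farthest from the median W share. With the W share as a covariate, the Z median of SF3B1 minus PHF5A was -0.0892 in place of -0.42. These values are consistent with a different mix of female (ZW) and male (ZZ) embryos in the pools, with control 2 almost free of W reads. The sex of the embryos is not given in the sources used here, and the W share also differs between groups, so a knockout effect on these chromosomes stays open as untested.

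In the span pattern, genes of 30 to 100 kb rose against those of up to 3 kb in all 6 knockout libraries, while the median of genes over 300 kb was -0.07 in SF3B1 knockout. Depth is argued against for the span difference, since the smallest of the 3 was 0.526 after thinning to the smallest total, while the controls lay at 0.0964 and -0.0964. Genes over 300 kb were not examined after thinning. Genomic DNA is argued against only for highly expressed genes of 30 to 100 kb in DLC1 and PHF5A knockout. The 10th percentile of CPM per kb over the 7034 features of 30 to 300 kb was 0 in each knockout. An even background at that level gives 0% of the observed change of those genes. The 25th percentile on assembled chromosomes gives 0.637% in DLC1 and 0.576% in PHF5A knockout. It gives 3.35% in SF3B1 knockout, where the observed median was only 0.037. Genes of lower expression were not tested in this way. Among those of lowest expression the long genes rose more, with medians of 0.444, 0.582 and 0.454 in DLC1, PHF5A and SF3B1 knockout, so genomic DNA stays open there. Within the 6 knockout libraries a lower mitochondrial share went with a larger span difference. Pearson r was -0.822 (exact permutation p = 0.0319) and Spearman rho -0.771 (exact permutation p = 0.103). With each knockout centred on its own mean, r was -0.998. The guide 1 library, however, had the lower share and the larger difference in all 3, so the relation also follows the guide number. Exchanging the libraries within knockouts gave a permutation p of 0.25, the smallest that 8 arrangements allow. A smaller part of cytoplasmic against nuclear, partly unspliced, RNA therefore stays open, whether from the knockout of splicing factors or from how cells were sorted and lysed, which gene-level counts do not separate; the DLC1 knockout shows the span pattern too.

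In the pattern of changes shared by the 3 knockouts, the shared controls do not account for all of it: the smallest covariance between 2 knockouts of their differences in mean log2 CPM from control, 0.361 (lower than with the fold changes of the edgeR fit), exceeded by 0.265 the 0.0956 that the measured difference between the controls gives. Total counts do not either, since 1110 genes were called in all 3 after thinning, against 1118 before. Independent lists would share 42.8, but that number is a weak yardstick, since lists that share their controls are not independent. Thinning equalises total counts and cannot undo a separate sequencing run. Separate handling of the control libraries cannot be told apart from a common response to the knockouts: both would set the controls apart, as the gap of 66.9 on the first principal component between the nearest knockout and control libraries does, the labels name no batch, and by total counts the SF3B1 libraries lay with the controls. A response common to cutting by Cas9 at any gene is also open, since a scrambled guide may cut nowhere; this was not tested.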

How the results depend on the processing

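Values with the W share as a covariate, with thinned counts and without mitochondrial, Z or W features come from alternatives chosen after the data were seen; the others were fixed before. The alternatives fixed for the lists of named genes and for the targeted genes were not run, since no names were at hand. Why a count moved under a setting was not tested.

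Leaving out each library in turn gave 302 to 3552 calls for DLC1, 2268 to 4534 for PHF5A and 149 to 3433 for SF3B1 knockout against control, 1430 to 5252 for the mean of the 3 and 110 to 1467 in all 3. It gave 0 to 69 between PHF5A and DLC1, 1 to 1636 between SF3B1 and DLC1 and 3 to 123 between SF3B1 and PHF5A knockout. A group left with 1 library was assumed to vary like the others. With the replicate block there were 4046 calls for SF3B1 knockout, 2078 in all 3, 11 between PHF5A and DLC1, 1823 between SF3B1 and DLC1 and 584 between SF3B1 and PHF5A knockout; the other counts stayed within 1.5 times. Same-numbered libraries deviated together with r between -0.221 and 0.281 over the 6 pairs of groups, and the numbers were not taken to pair the samples. The guide 1 library held the lower mitochondrial share in each knockout, so handling that follows the numbers is not excluded.

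With library size only, SF3B1 gave 3951 calls, all 3 gave 2002, and the knockout pairs gave 0 (PHF5A and DLC1), 329 (SF3B1 and DLC1) and 52 (SF3B1 and PHF5A). With no filter the values were 4056, 1933, 722, 2578 and 1134 in that order, and the span differences were 0.314 (DLC1), 0.394 (PHF5A) and 0.159 (SF3B1). At a mean of at least 5 CPM, PHF5A and DLC1 differed in 0 genes and SF3B1 and DLC1 in 474, and the span difference of DLC1 was 0.820. DESeq2 gave 280, 1866 and 664 and the pairs fitted alone 73, 1949 and 0 for the 3 knockout pairs; limma-voom gave 2 for PHF5A and DLC1, and leaving out Z and W features 8. The W share as a covariate gave 1839 calls for DLC1 and 2 for SF3B1 knockout, 2 in all 3, and 0, 16 and 0 for the knockout pairs, and brought the Z median of SF3B1 minus PHF5A to -0.0892. Where 0 genes were called, edgeR gave 725 to 2505 genes at an unadjusted p under 0.05.

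The agreement of the 2 guides was 0.649 for DLC1 and 0.584 for PHF5A with the controls exchanged, 0.817, 0.840 and 0.838 for DLC1, PHF5A and SF3B1 against the mean of the controls, which both then share, and 0.615 for DLC1 and 0.756 for SF3B1 at a mean of at least 5 CPM. Among the 12 values of named genes, 237 alternatives kept the call, 13 lost it and 0 reversed the sign; 2 gave no adjusted p for ENSGALG00000040296, which they left out of the test. At the depth of these libraries and with 2 per group, 26% of simulated 2-fold changes were recovered. That simulation changed only 50 of 15619 genes at each fold. The knockouts against control had 16.1% to 31.3% of genes called, where the Benjamini-Hochberg cutoff is looser, so recovery there can differ.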

Other observations

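ENSGALG00000030129 was the 1 feature of 30862 with 0 reads in both controls and at least 50 in each of the 6 knockout libraries, where it held between 97 and 528. The reverse, at least 50 reads in both controls and 0 in all 6 knockouts, occurred for 0 features. ENSGALG00000048209 came close, with 3 and 5 reads in the controls and 356 to 940 in the knockouts, at nearly equal CPM in the 3 knockouts (24.8 ± 4.51, 21.1 ± 3.57 and 19.1 ± 0.0325; SD, n = 2 each). This count of features read in the knockouts alone was chosen after the values were seen.

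The 2 features that fell most in DLC1 knockout, among those passing the rule for named genes, fell by a similar amount in PHF5A knockout and stood higher in SF3B1 knockout. ENSGALG00000030994 stood at 0.791 ± 0.102, 0.797 ± 0.241 and 9.01 ± 2.74 CPM in DLC1, PHF5A and SF3B1 knockout, against 14.7 ± 0.778 in control (SD, n = 2 each), and ENSGALG00000056015 at 2.76 ± 0.427, 1.78 ± 0.427 and 9.27 ± 0.863, against 27 ± 0.912. Both differed between SF3B1 and each of the other knockouts (edgeR adjusted p between 0.00317 and 0.0164). Between SF3B1 and PHF5A knockout both calls were lost with only these groups in the fit and with the W share as a covariate, where 0 genes were called. Between SF3B1 and DLC1 knockout the 2 features were not followed one by one across the alternatives. Of the 778 calls of that comparison, 16 were kept with the W share as a covariate. The number of calls also fell when libraries of either knockout were left out, so these 2 calls cannot be taken as stable. ENSGALG00000000302 varied widely between replicates outside PHF5A knockout, with 439 and 1322 reads in the controls and 1915 and 625 in the DLC1 libraries, against 16 and 12 in PHF5A knockout.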
